A study of Mus musculus with 12 samples.

How the data were processed

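RNA sequencing was done on subcutaneous colorectal tumour tissue from mice in 4 groups of 3 libraries: control, chronic stress, and chronic stress with a low or a high dose of Xiao-chai-hu decoction. Per the labels, total RNA with an integrity number above 7 was selected for poly(A), and stranded libraries were read from both ends. The authors trimmed reads with cutadapt 1.9, aligned them to GRCm38.p6 with HISAT2 2.0.4 and assembled transcripts with StringTie 1.3.4d. Per the labels they also used DESeq2 and edgeR, without versions, and the labels give neither the annotation, the counting options nor any filter. The deposited estimated counts were made by the authors per gene without further scaling, and 11.7% to 12.5% of the values in each library were not whole numbers. They were rounded here, although whole counts had been assumed before the data were examined. The deposited FPKM values were scaled by the authors for gene length and library size. The deposited TPM values were scaled by the authors so that each library had the same sum over the genes of the table. FPKM served only to choose named genes and check units, and TPM only to check units.

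Symbols that a spreadsheet had turned into dates were restored for 26 genes, and 17820 genes were matched by Entrez ID to the reference annotation, 17714 of them protein coding. No mitochondrially encoded gene was in the tables. The median SE of a log2 fold change between groups was 0.164.

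Genes were kept with edgeR's filterByExpr at a minimum count of 10, which left 13453. TMM factors and edgeR 4.0.16 quasi-likelihood tests with robust fitting were used in R 4.3.3, in 1 model of all 12 libraries with 4 groups. The residual degrees of freedom were 8 and the common dispersion 0.038. The p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05 on the adjusted value. The 6 comparisons were stress with control, each dose with stress, the doses with each other, and each dose with control. Tests were 2-sided.

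Gene lists were written before the data were examined: 52 lists with 1150 entries, of which 1073 matched by symbol, 21 by synonym, 8 repeated a member of their list and 48 were absent; 51 lists had at least 3 members tested. They covered stress hormone responses, cell division and death, metabolism, stress and inflammatory pathways, growth signalling, immune, stromal and contaminating cell types, drug targets and sample checks. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. Scores were the mean centred log2 CPM of a list's members with a prior count of 2. The opposition of the stress and dose responses was measured as the covariance across genes of the log2 fold changes, set beside 20 simulations without effects, with all libraries and without each in turn, and beside the 6 ways of using different stress libraries on each side.

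The tests, lists, comparisons and the rule for named genes were fixed before the data were examined. By that rule, genes passing in a comparison were named, up to 10 per direction. They needed a mean FPKM of at least 1 in the higher group, an official symbol and no overlap between the groups. Where too few passed, up to 5 per direction with the smallest unadjusted p were given as values that did not pass. Up to 3 members were named for a list that passed camera, and at most 2 for lists that did not pass but bear on the question of the study. A few genes outside the rule are named as such.

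Alternatives fixed beforehand were DESeq2 1.42.0, limma-voom with quality weights, RLE factors, no filter, a minimum count of 50, only the 6 libraries compared, the replicate number as a block, an unadjusted p under 0.05 with an absolute log2 fold change of at least 1, and each library left out in turn. With 1 library left out, 2 libraries stood for its group and the spread was pooled over all groups. The filter was rerun, so list members may differ. Alternatives chosen after the data were seen were the skeletal muscle score as a covariate, omission of the 3 libraries with the most muscle transcripts, and offsets that removed each library's trend with transcript length and GC content. The offsets were a loess fit with a span of 0.3 on genes with a mean log2 CPM above 1. The replicate numbers were not used for pairing, because nothing in the labels pairs the animals and only 4 of 12 libraries correlated best with a library of their own number.

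The pipeline was tested on simulated changes between stress and control. It called 19.4% of genes changed 1.5-fold, 70.1% at 2-fold and 90.9% at 4-fold, and 2 unchanged genes. DESeq2 called 34.3%, 76.1% and 95.5%, and 39 unchanged genes. A list raised by 0.5 on the log2 scale was called with an adjusted p of 3.83e-17, and 0.000532 with an estimated correlation. A real rise of 0.62 (hypoxia, low dose against stress) had 0.616 by the latter, so power for real lists may be lower. A covariance of -0.0709 was recovered as -0.0668. Splicing, transcript isoforms and raw reads were not analysed.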

Results

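Messenger RNA was measured by sequencing in subcutaneous colorectal tumour tissue from mice, in 12 libraries that fell into 4 groups of 3. The groups were a control group with tumours alone, a group under chronic stress, and a low-dose and a high-dose group that were under chronic stress and received Xiao-chai-hu decoction, a multi-herb preparation of traditional Chinese medicine. The labels gave neither the doses in numbers nor the tumour cell line. The total count per library ran from 16734741 to 17950195, and 15476 to 15775 genes had a count above 0. Nothing in the labels states that the 3 replicates of a group came from separate animals, so the p-values measure only the spread between these libraries, part of which may be technical. Pairs of libraries of a group had dispersion indices, the chi-square of their counts per gene, from 6.55 to 80.9, so none agreed within counting noise. All sizes are log2 fold changes with their standard error (SE), with 3 libraries per group; expression levels are counts scaled to library size (CPM), as mean ± SD with n = 3. Genome positions refer to GRCm38.p6.

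Transcripts of mature muscle fibres separated 3 libraries from the rest, and these came from 3 different groups. Acta1, which encodes skeletal muscle actin, stood at 64.2 CPM in control replicate 1, at 52 CPM in low-dose replicate 3 and at 125 CPM in high-dose replicate 2, and at 0.1 to 8.2 CPM in the other libraries. The skeletal muscle score, the mean centred log2 CPM of 25 genes, was 3.12, 2.5 and 3.83 in those libraries. The first principal component held 31.4% of the variance and the second 18.9%. A separate difference ran along gene length: across genes, the correlation of a library's deviation from the mean library with transcript length ranged from -0.61 in low-dose replicate 2 to 0.4 in high-dose replicate 3, where genes are not independent replicates. Low-dose replicate 1 stood at 0.06 and low-dose replicate 3 at -0.22, while the stress libraries stood at 0.16, 0.24 and 0.14.

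**Figure D1:**
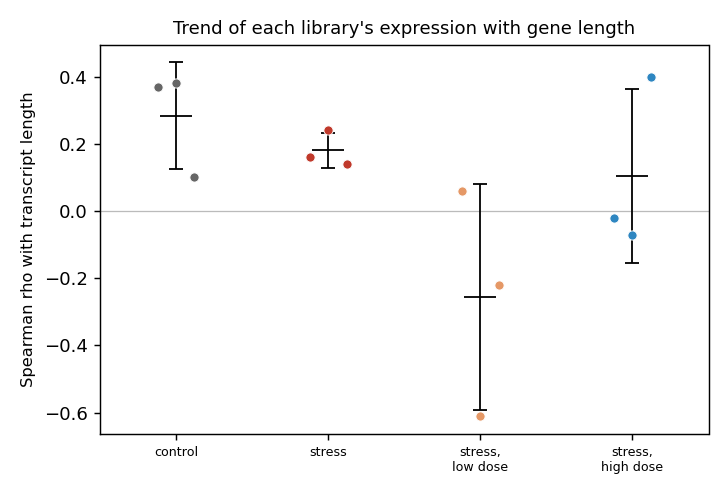
Spearman correlation, across 11790 genes, of each library's log2 CPM relative to the mean library with transcript length, by group; points are the 3 libraries of a group and bars are mean ± SD. Low-dose replicate 2 had the lowest value at -0.61, and the control libraries stood at 0.37, 0.38 and 0.1.

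Tumours of stressed mice were compared with control tumours to ask what chronic stress alone did to tumour gene expression. Genes induced by glucocorticoids, the adrenal hormones released under stress, were higher in the stress group: the median log2 fold change of the 17 list members was 0.24, and 14 of the 17 were higher. Cebpd, a transcription factor induced by glucocorticoids and cytokines, stood at 14.2 ± 3.51 CPM under stress and 6.74 ± 0.444 CPM in controls. The log2 fold change of Cebpd was 1.08 (SE 0.31). Per1, a clock gene that the glucocorticoid receptor also switches on, differed by 0.71 (SE 0.22), and Sgk1, a kinase induced by glucocorticoids, by 0.78 (SE 0.25), or 0.36 without stress replicate 3. Targets of cyclic AMP signalling, the pathway downstream of beta-adrenergic receptors, were higher by a median of 0.40 in 11 of 13 members. Among them, Tfrc, the transferrin receptor for iron uptake, stood at 1.19 (SE 0.37), or 0.69 without that library. Hypoxia-response genes were lower in 20 of 21 members, with a median of -0.30. Ankrd37, a hypoxia-induced ankyrin repeat gene, stood at -0.98 (SE 0.41) and Vegfa, the main growth factor for blood vessels, at -0.60 (SE 0.31), or -0.39 without stress replicate 3. TGF-beta targets were lower in 13 of 17 members, with a median of -0.21. Pmepa1, a feedback inhibitor of the pathway, stood at -0.45 (SE 0.15).

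These 4 lists passed camera with a preset correlation between genes. The glucocorticoid list rose with an adjusted p of 9.74e-05, the cAMP list rose with 8.77e-05, the hypoxia list fell with 3.34e-06 and the TGF-beta list fell with 0.000529. With an estimated correlation the adjusted p = 0.196 for the glucocorticoid and cAMP lists, adjusted p = 0.56 for hypoxia and adjusted p = 0.317 for TGF-beta, and fry, which tests each list by rotation, called 0 of the lists. These 4 calls held without any 1 of the 6 libraries, where the adjusted p ranged from 4.5e-14 to 0.0136, but sizes moved. The hypoxia median was -0.78 without stress replicate 2, whose score of 0.17 lay above those of 2 of the 3 controls, and -0.20 without stress replicate 1, and the cAMP median was 0.23 without stress replicate 3. The 4 lists also held with the muscle score as a covariate, which ended 6 of the other 17 calls, and with length and GC trends removed. Over all alternatives the adjusted p ranged from 2.87e-05 to 0.412 for glucocorticoid genes, from 7.93e-07 to 0.412 for cAMP, from 4.5e-14 to 0.935 for hypoxia and from 4.33e-05 to 0.412 for TGF-beta. Sgk1, Cebpd and Per1 passed when adjusted over the list alone, where 3 of 17 glucocorticoid genes did, and 0 of 17 passed over all genes. For hypoxia, cAMP and TGF-beta genes, 0 members passed adjusted over the list alone and 0 over all genes.

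Of the other 17 lists called in this comparison, each lost its call without at least 1 library. The macrophage list rose by a median of 0.34. Its median was 0.29 without control replicate 3 and 0.18 without stress replicate 1 or 2. The call ended in each case (adjusted p = 0.0619, 0.111 and 0.108). The list of cytotoxic lymphocytes and natural killer cells rose by a median of 0.47 in 21 of 22 members, and without stress replicate 1 the median was 0.01 (adjusted p = 0.732), and 0.92 without stress replicate 3. The mast cell list rose by 0.66 and by 0.46 without stress replicate 3 (adjusted p = 0.168). Without any 1 of the others it rose by 1.27 to 1.72, where its members may differ. The dendritic cell list rose by 0.43, and by 0.12 without stress replicate 1 (adjusted p = 0.653), and by 0.24 without control replicate 3 (adjusted p = 0.177). The adjusted p of these lists over all alternatives ranged from 2.82e-09 to 0.988 for macrophages, from 3.28e-26 to 0.988 for cytotoxic cells, from 1.21e-06 to 0.839 for mast cells and from 0.00146 to 0.988 for dendritic cells. With an estimated correlation the adjusted p = 0.763 for macrophages, cytotoxic cells and dendritic cells and adjusted p = 0.527 for mast cells.

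Among the lists that fell, skeletal muscle had a median of -1.93, with Myh7, a slow-fibre myosin, at -3.42 (SE 2.05). Without control replicate 1, 1 of the 3 libraries rich in muscle transcripts, the list median was 0.37 (adjusted p = 0.599) and Myh7 stood at 1.15; with the muscle score as a covariate the median was 0.07 (adjusted p = 0.711), and without stress replicate 1 the median was -4.6. The colorectal epithelial list had a median of -0.28, with Sox9, a transcription factor of crypt cells, at -0.57 (SE 0.17). Sox9 passed when adjusted over the list alone as 1 of 8 members against 0 over all genes. The list median was -0.27 without stress replicate 1 and -0.15 without stress replicate 3, and the call ended (adjusted p = 0.0591 and 0.0963); without stress replicate 2 it was -0.54. Glycolysis enzymes fell by 0.22 and had a median of -0.15 without stress replicate 3 (adjusted p = 0.0533), -0.35 without control replicate 1 and -0.45 without stress replicate 2. Heat shock proteins fell by 0.13 and had a median of -0.03 with the muscle score as a covariate (adjusted p = 0.0894), -0.05 without control replicate 3 (adjusted p = 0.0816) and -0.22 without control replicate 2. Output genes of the ERK pathway fell by 0.25. The ERK median was -0.14 without stress replicate 1 and -0.21 without stress replicate 2, and the call ended (adjusted p = 0.118 and 0.107). The adjusted p of these 5 lists over all alternatives ranged from 4.03e-12 for muscle to 0.988 for muscle, glycolysis and heat shock proteins. With an estimated correlation the adjusted p = 0.786 for skeletal muscle and heat shock proteins, adjusted p = 0.326 for the epithelial list, adjusted p = 0.763 for glycolysis and adjusted p = 0.56 for ERK output. Of the remaining 8 called lists, genes of the unfolded protein response rose by a median of 0.10, and the other 7 fell, with medians from -0.32 for skin genes to -0.05 for nerve genes; none of the 8 held with an estimated correlation (adjusted p = 0.326 to 0.957).

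No single gene passed edgeR's test for stress against control at an adjusted p under 0.05, the smallest adjusted p being 0.9999. At an unadjusted p under 0.05 there were 383 genes, 148 higher and 235 lower, where 673 of the 13453 tested would pass by chance. That count depended on the fit: it was 1051 with only the 6 libraries compared (smallest adjusted p = 0.0815) and 1350 by limma-voom with quality weights (0.0663), which both called 0 genes. DESeq2 called 1 gene. That gene was Mgat3 (Entrez ID 17309, chromosome 15, 80173651 to 80215519), the enzyme that adds the bisecting sugar to N-glycans. It stood at 112 ± 12.5 CPM under stress and 166 ± 19.3 CPM in controls, a log2 fold change of -0.56 (SE 0.11). The other 4 genes with the smallest p among those lower were Dlx3, a homeobox factor of epithelia, at -0.62 (SE 0.13), Rasgef1a, a guanine nucleotide exchange factor, at -1.47 (SE 0.32), Card10, a scaffold of NF-kappa-B activation, at -1.15 (SE 0.25), and Plekha6 at -0.82 (SE 0.18). Among those higher were Cebpd, Hcst, an adaptor of natural killer cells, at 1.66 (SE 0.46), and Lrp4, a receptor of agrin, at 1.19 (SE 0.34), or 0.72 without stress replicate 3. The 3 libraries of one group did not overlap those of the other for 14.1% of genes, against 10% by chance.

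**Figure D2:**
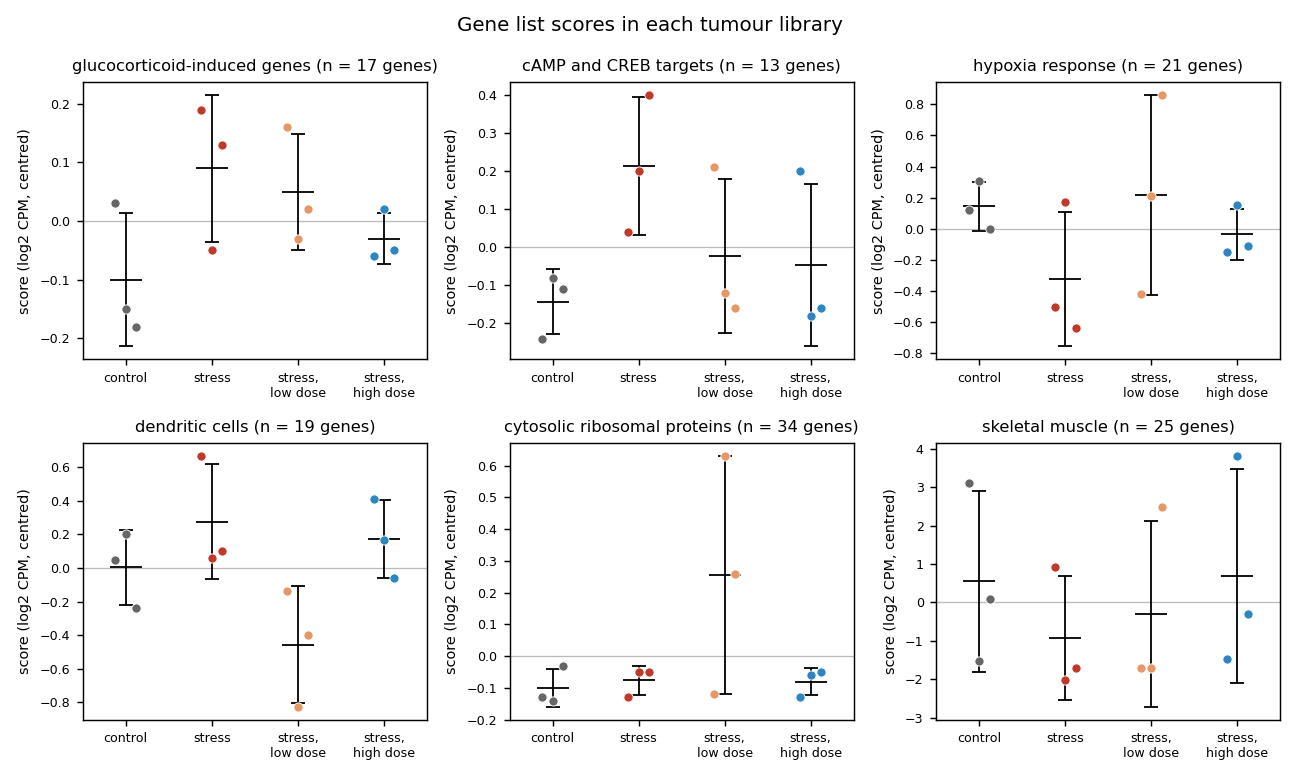
Mean centred log2 CPM of the members of 6 gene lists in each library, by group; points are the 3 libraries of a group and bars are mean ± SD. The cAMP scores were 0.04, 0.2 and 0.4 in the stress libraries and -0.24, -0.08 and -0.11 in the controls, and the ribosomal protein score was -0.12, 0.63 and 0.26 in the low-dose libraries.

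Low-dose tumours were compared with stress tumours to ask what the decoction did at its lower dose. Genes that mark dendritic cells, the antigen-presenting cells that prime T cells, were lower in 15 of 19 members, with a median of -0.97. Flt3, the receptor that drives their development, stood at -2.30 (SE 0.70), Ccl22, a chemokine they secrete, at -1.38 (SE 0.40), and Ccr7, the receptor that guides them to lymph nodes, at -1.60 (SE 0.47). Immediate early genes, which respond within minutes to growth factors or handling, were higher by a median of 0.51 in 21 of 23 members. Ier3 stood at 1.72 (SE 0.48), or 0.89 without low-dose replicate 3, and the AP-1 subunit Junb at 0.60 (SE 0.21). Heat shock proteins, the chaperones of protein folding, were higher by 0.45 in 18 of 19 members. All 34 cytosolic ribosomal protein genes were higher, by a median of 0.38, with Rps14 at 0.63 (SE 0.16). Of the 31 oxidative phosphorylation genes, 29 were higher, by a median of 0.25.

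In camera with the preset correlation the dendritic cell list fell with an adjusted p of 5.6e-05, and the immediate early, heat shock, ribosomal and oxidative phosphorylation lists rose with adjusted p-values of 4.94e-06, 1.97e-07, 4.44e-14 and 2.26e-09. Glycolysis enzymes rose by a median of 0.50 (adjusted p = 5.6e-05), and targets of Nrf2, the regulator of antioxidant genes, rose by 0.26 (adjusted p = 0.00291). For each of the 7 lists the adjusted p = 0.616 with an estimated correlation, the highest value over all alternatives. These 7 calls held without any 1 of the 6 libraries, where the adjusted p ranged from 1.37e-24 for ribosomal genes to 0.0414 for Nrf2 targets, but sizes depended on single libraries. Low-dose replicate 1 stood apart from replicates 2 and 3, with ribosomal scores of -0.12, 0.63 and 0.26 against a stress mean of -0.08 and glycolysis scores of -0.37, 0.42 and 0.57 against -0.21. Without low-dose replicate 2 the median was 0.17 for ribosomal, 0.15 for oxidative phosphorylation, 0.33 for glycolysis and -0.62 for dendritic cell genes. It was 0.77 without low-dose replicate 1 for glycolysis and 0.26 for immediate early genes, and without stress replicate 1 it was 0.32 for immediate early and -0.47 for dendritic cell genes. With each library's length and GC trends removed, the ribosomal median was 0.11 and the oxidative phosphorylation median 0.06, while the dendritic cell median was -0.93. Adjusted over the list alone, 4 of 19 dendritic cell genes passed (Flt3, Itgae, Ccl22 and Ccr7) and 5 of 31 oxidative phosphorylation genes, against 0 of each over all genes. For the other 5 lists of this paragraph 0 members passed either way.

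The other 6 lists called for the low dose each lost the call without at least 1 library. Hypoxia-response genes rose by a median of 0.62, and by 0.26 without low-dose replicate 3 (adjusted p = 0.0872), 1 of the libraries rich in muscle transcripts, and by 1.08 without stress replicate 2. TGF-beta targets rose by 0.22, with Pmepa1 at 0.64 (SE 0.15) and Tgfbi at 0.44 (SE 0.12), the 2 of 17 members that passed when adjusted over the list alone against 0 over all genes. The TGF-beta median was 0.20 without stress replicate 3, 0.43 without low-dose replicate 1 and 0.14 without low-dose replicate 3, and the call ended (adjusted p = 0.0823, 0.0612 and 0.0543). Autophagy and lysosome genes rose by 0.21, and by 0.11 without low-dose replicate 2 (adjusted p = 0.137); without stress replicate 1 the median was 0.17 (adjusted p = 0.0507). Cholesterol synthesis genes fell by 0.35 and had a median of -0.05 without stress replicate 3 (adjusted p = 0.663). Without low-dose replicate 1 the cholesterol median was -0.26 (adjusted p = 0.224), and -0.525 without stress replicate 2. Genes of cell division in G2 and M phase fell by 0.17 and had a median of -0.04 without low-dose replicate 1 (adjusted p = 0.802). Without stress replicate 3 the G2 and M median was -0.000469 (adjusted p = 0.663); it was -0.30 without stress replicate 2, -0.105 without low-dose replicate 2 and -0.36 without low-dose replicate 3. The type I interferon list fell by 0.51 and had a median of -0.12 without stress replicate 2 (adjusted p = 0.951), where camera gave the opposite direction. Without low-dose replicate 2 the interferon median was -0.35 (adjusted p = 0.0514), and -0.895 without stress replicate 3. The adjusted p of these 6 lists over all alternatives ranged from 1.08e-19 to 0.951, both for the interferon list. For these lists, with an estimated correlation, the adjusted p = 0.616 for hypoxia, TGF-beta and autophagy and adjusted p = 0.784 for cholesterol, G2 and M phase and type I interferon genes.

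No gene passed edgeR's test for the low dose against stress with all libraries, the smallest adjusted p being 0.205, while 1796 genes had an unadjusted p under 0.05 (915 higher and 881 lower) against 673 by chance. That count was 797 with only the 6 libraries compared, 1109 without low-dose replicate 2 and 3874 without low-dose replicate 1. Other ways of splitting the 6 libraries, 3 against 3, gave 436 to 2901 such genes. The excess over 673 therefore does not by itself show an effect of the dose. DESeq2 called 95 genes, 55 higher and 40 lower, and limma-voom with quality weights called 0. Without low-dose replicate 1, edgeR called 1244 genes, 635 higher and 609 lower, and the same without that library but with length and GC trends removed called 175. Of the 10 genes taken for their small unadjusted p, the one with the largest difference was Dnase1l3 (Entrez ID 13421, chromosome 14, 7965187 to 7994760), a secreted DNase made by dendritic cells and macrophages. It stood at 0.287 ± 0.255 CPM in the low-dose group and 3.45 ± 1.22 CPM under stress, a log2 fold change of -3.55 (SE 0.55). Notch3 (Entrez ID 18131, chromosome 17, 32120820 to 32166896), a receptor of vascular smooth muscle, stood at 6.64 ± 1.55 CPM and 13.9 ± 1.19 CPM, a log2 fold change of -1.06 (SE 0.18). Etl4 at -0.68 (SE 0.12), Tbc1d8, of a family that switches off Rab GTPases, at -0.79 (SE 0.15), and Tnrc6a, a scaffold of microRNA silencing, at -0.49 (SE 0.10) were the others among those lower. Those higher were Vamp5, a vesicle fusion protein, at 0.75 (SE 0.14), Sdc1, the proteoglycan syndecan-1, at 0.49 (SE 0.10), Cyp26b1, which degrades retinoic acid, at 1.05 (SE 0.21), Pdlim7, a protein of the actin cytoskeleton, at 0.70 (SE 0.14), and St3gal5, which makes the ganglioside GM3, at 1.01 (SE 0.21). All 10 passed DESeq2 and passed edgeR without low-dose replicate 1, and 6 of the 10 passed without that library once length and GC trends were removed. The groups did not overlap for 11.9% of genes, against 10% by chance.

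**Figure D3:**
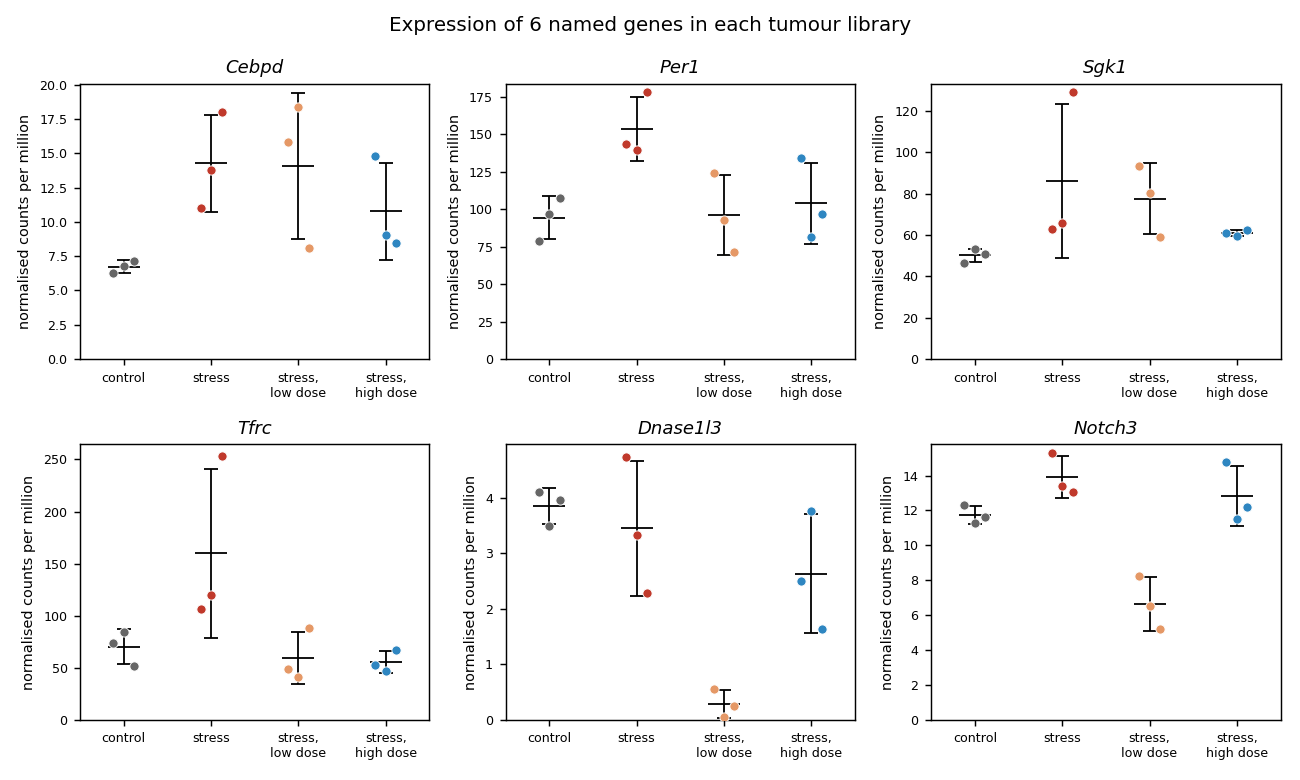
Library-scaled counts (CPM) of 6 genes in each library, by group; points are the 3 libraries of a group and bars are mean ± SD. Dnase1l3 stood at 0.287 in the low-dose group against 3.45 under stress, and Tfrc at 160 under stress against 70.2 in controls and 55.4 in the high-dose group.

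High-dose tumours were compared with stress tumours to ask what the decoction did at its higher dose. Heat shock proteins were higher by a median of 0.32 in all 19 members, with the small chaperone Hspb1 at 1.80 (SE 0.81), or 0.38 without high-dose replicate 2. Glucocorticoid-induced genes were lower in 14 of 17 members, with a median of -0.13. Per1 stood at 104 ± 27.1 CPM against 154 ± 21.5 CPM under stress, a log2 fold change of -0.56 (SE 0.22). Targets of cyclic AMP were lower in 8 of 13 members, with a median of -0.13, and Tfrc stood at 55.4 ± 10.6 CPM against 160 ± 81.3 CPM, a log2 fold change of -1.53 (SE 0.38), or -1.02 without stress replicate 3. Nrf2 targets were higher by 0.18 in 14 of 19 members, with Hmox1, the enzyme that breaks down heme, at 1.44 (SE 0.45), or 0.85 without high-dose replicate 1.

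In camera with the preset correlation the heat shock list rose (adjusted p = 7.38e-12) and the glucocorticoid list fell (adjusted p = 0.000735). With an estimated correlation the adjusted p = 0.506 and 0.456. These calls held without any 1 of the 6 libraries. The glucocorticoid median was -0.285 without stress replicate 2 and -0.21 without high-dose replicate 2. Over all alternatives the adjusted p ranged from 2.12e-15 to 0.959 for heat shock proteins and from 0.000476 to 0.959 for glucocorticoid genes. The heat shock score in high-dose replicate 2 was 0.6 against -0.06 and -0.22 in the other high-dose libraries. The list median was 0.11 both without that library and without the 3 libraries rich in muscle transcripts. The cAMP list fell (adjusted p = 0.00462; adjusted p = 0.506 with an estimated correlation), with 1 of 13 members, Tfrc, passing when adjusted over the list alone and 0 over all genes. The cAMP median was -0.04 without stress replicate 3 and -0.10 without high-dose replicate 3, and the call ended (adjusted p = 0.0573 and 0.118); it was -0.20 without stress replicate 2, -0.25 without high-dose replicate 1 and -0.08 without high-dose replicate 2. The Nrf2 list rose (adjusted p = 0.000282; adjusted p = 0.525 with an estimated correlation) and had a median of 0.155 without stress replicate 1 (adjusted p = 0.0502), 0.10 without high-dose replicate 2 and 0.27 without high-dose replicate 3. Endothelial genes rose by 0.30, and by 0.06 without stress replicate 2 (adjusted p = 0.506), 0.51 without stress replicate 3 and 0.14 without high-dose replicate 2; with an estimated correlation the adjusted p = 0.679. TGF-beta targets rose by 0.21, and by 0.05 without high-dose replicate 2 (adjusted p = 0.148). Without stress replicate 3 the TGF-beta median was 0.20 (adjusted p = 0.064), and with an estimated correlation the adjusted p = 0.506. Without the 3 libraries rich in muscle transcripts the Nrf2 and TGF-beta calls ended (adjusted p = 0.0573 and 0.206). The adjusted p of the cAMP, Nrf2, endothelial and TGF-beta lists over all alternatives ranged from 1e-09 for endothelial genes to 0.959 for each list. For the heat shock, glucocorticoid, Nrf2, endothelial and TGF-beta lists 0 members passed adjusted over the list alone.

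Skeletal muscle genes rose by a median of 2.67. The median was -0.42 without high-dose replicate 2 (adjusted p = 0.813) and 5.31 without stress replicate 1. T cell genes fell by 0.42 and stood at 0.18 without stress replicate 1 (adjusted p = 0.0646). The T cell median was -0.50 without stress replicate 2 and -0.21 without high-dose replicate 3 (adjusted p = 0.127 and 0.58), -0.72 without stress replicate 3 and -0.25 without high-dose replicate 2. Hypoxia genes rose by 0.13 and by 0.03 without stress replicate 1 (adjusted p = 0.349), and had a median of -0.00538 without stress replicate 3 (adjusted p = 0.571) and 0.53 without stress replicate 2. The epithelial list rose by 0.27 and the ERK list by 0.17. The epithelial median was 0.24 without stress replicate 1, 0.14 without stress replicate 3, 0.17 without high-dose replicate 2 and 0.20 without high-dose replicate 3, and each ended the call (highest adjusted p = 0.541). The ERK median was 0.13 without stress replicate 1, 0.16 without stress replicate 2, 0.25 without high-dose replicate 1 and 0.07 without high-dose replicate 2, and each ended the call (highest adjusted p = 0.388); it was 0.31 without stress replicate 3. With the muscle score as a covariate the muscle, hypoxia, ERK and epithelial calls ended (highest adjusted p = 0.604), and without the 3 libraries rich in muscle transcripts all but hypoxia did (highest adjusted p = 0.959). The adjusted p of these 5 lists over all alternatives ranged from 1.22e-13 for T cells to 0.959 for each list. For these lists, with an estimated correlation, the adjusted p = 0.679 for muscle and ERK output, adjusted p = 0.852 for T cells and hypoxia, and adjusted p = 0.525 for the epithelial list.

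No gene passed edgeR's test for the high dose against stress (smallest adjusted p = 0.9998), DESeq2 and limma-voom with quality weights each called 0, and 191 genes had an unadjusted p under 0.05 (111 higher and 80 lower) against 673 by chance. Tfrc (Entrez ID 22042, chromosome 16, 32608896 to 32632794) led those lower, followed by Tmem254c at -3.77 (SE 1.09), or -1.16 without stress replicate 1, which has close paralogs in the same cluster. The first of those higher were AA414768 at 0.71 (SE 0.17) and the tetraspanin Tspan7 at 0.88 (SE 0.22). The groups did not overlap for 5.75% of genes, against 10% by chance.

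Whether the decoction moved genes against the direction of stress was asked across all 13453 genes. The covariance of the stress change with the low-dose change was -0.0736, and with the high-dose change -0.0808, but both share the stress libraries, which alone makes it negative. In 20 simulations without any effect the mean covariance was -0.0619 (-0.0739 to -0.0465) for the low dose and -0.0626 (-0.0786 to -0.0496) for the high dose. The low-dose value lay within the simulated range and the high-dose value just below it. With different stress libraries on each side, all 6 ways gave negative covariances for each dose. They ran from -0.0526 to -0.0122 for the low dose and from -0.0706 to -0.0334 for the high dose. Genes are not independent replicates, so no p-value is given. With 1 library left out, simulations without any effect were made anew. The low-dose covariance was -0.228 without stress replicate 1 (simulated -0.133 to -0.102), -0.1255 without stress replicate 2 (-0.13 to -0.0997), -0.118 without low-dose replicate 1 (-0.0852 to -0.0595) and -0.01005 without low-dose replicate 3 (-0.0749 to -0.0524). The high-dose covariance was -0.2794 without stress replicate 1 (-0.136 to -0.104), -0.1327 without stress replicate 2 (-0.13 to -0.0967), -0.1361 without high-dose replicate 1 (-0.082 to -0.0603), -0.04764 without control replicate 1 (-0.0794 to -0.0591) and -0.02606 without high-dose replicate 2 (-0.0707 to -0.0553). Values thus lay on both sides of the simulated range, depending on the library left out, so lying outside it does not show opposition. Of the single genes, Per1 was higher under stress by 0.71 and stood lower at the low dose, at -0.68 (SE 0.22), and at the high dose, at -0.56 (SE 0.22), all against the same stress libraries. The glucocorticoid list as a whole was not called for the low dose against stress (adjusted p = 0.512): 10 of 17 members were lower, with a median of -0.031 and a mean of 0.068. Nor was the cAMP list, with a median of -0.26 (adjusted p = 0.138).

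The doses were compared with each other to test their difference. Dendritic cell genes were higher at the high dose by a median of 0.72 in 15 of 19 members, with Zbtb46, a transcription factor of conventional dendritic cells, at 0.57 (SE 0.18). Endothelial genes were higher by 0.45 in 21 of 24, and genes of pericytes and smooth muscle, the cells that wrap vessels, by 0.64 in 11 of 14. Among them Notch3 stood at 12.8 ± 1.72 CPM against 6.64 ± 1.55 CPM, a log2 fold change of 0.95 (SE 0.18). Immediate early genes were lower with a median of -0.50 in 22 of 23, with Junb at -0.87 (SE 0.21) and Ier2 at -1.08 (SE 0.26), ribosomal protein genes with -0.40 in 33 of 34, with Rps14 at -0.65 (SE 0.16), and oxidative phosphorylation genes with -0.22 in 30 of 31.

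The dendritic, endothelial and pericyte lists rose in camera with adjusted p-values of 1.24e-05, 1.24e-05 and 0.000468, and the immediate early, ribosomal and oxidative phosphorylation lists fell with 2.16e-11, 8.85e-23 and 9.18e-10. With an estimated correlation the adjusted p = 0.579, 0.823, 0.579, 0.396, 0.623 and 0.823, and the highest value over all alternatives was 0.828, for endothelial genes by fry. These 6 calls held without any 1 of the 6 libraries, where the adjusted p ranged from 4.34e-34 for ribosomal genes to 0.0412 for pericytes. With length and GC trends removed, the ribosomal median was -0.185 and the oxidative phosphorylation median -0.0554. Without low-dose replicate 2 the median was -0.18 for ribosomal, -0.135 for oxidative phosphorylation, 0.25 for endothelial, 0.45 for dendritic cell and 0.38 for pericyte genes. The oxidative phosphorylation median was -0.34 without low-dose replicate 1, the pericyte median 0.42 without high-dose replicate 1, and without high-dose replicate 2 the medians were 0.39 for pericytes and 0.29 for endothelial genes. The other 8 lists called in this comparison lost the call without at least 1 library. Adjusted over the list alone, Ier2 and Junb passed as 2 of 23, Notch3 as 1 of 14 and Rps14 as 1 of 34, against 0 of each over all genes. No gene passed edgeR's test (smallest adjusted p = 0.549), with 860 genes at an unadjusted p under 0.05 (370 higher and 490 lower), or 308 with only the 6 libraries compared, 463 without low-dose replicate 2 and 3026 without low-dose replicate 1, against 673 by chance, 5 called by DESeq2 and 0 by limma-voom with quality weights; without low-dose replicate 1 edgeR called 99, but 0 once length and GC trends were removed and 369 with the muscle score as a covariate. The 5 were Notch3, Dnase1l3, Gm20594, Tlr12 and Tmem254c, and all except Notch3 were named here only after their values were seen; Gm20594 and Tmem254c were lower at the high dose. Others with a small p were Etl4 at 0.54 (SE 0.12), the laminin receptor Itga6 at 0.70 (SE 0.16), Siglec15, a sialic acid receptor of myeloid cells, at -2.68 (SE 0.67), or -1.20 without low-dose replicate 3 (11.078 CPM, against 1.405 and 2.07 in the other low-dose libraries), and Rpl17 at -0.53 (SE 0.14). The groups did not overlap for 7.34% of genes, against 10% by chance.

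Each dose was also compared with control tumours, to ask what differed after treatment. In low-dose tumours, ribosomal protein genes were higher by a median of 0.39 in all 34 members, oxidative phosphorylation genes by 0.27 in 30 of 31, immediate early genes by 0.50 in 22 of 23, Nrf2 targets by 0.36 in 17 of 19 and autophagy and lysosome genes by 0.27 in 17 of 24. Cholesterol synthesis genes were lower with a median of -0.49 in 21 of 22, and type I interferon genes with -0.48 in 25 of 27. These 7 lists passed camera and held without any 1 of the 6 libraries, with adjusted p-values from 0.00194 for the interferon list to 5.51e-17 for the ribosomal list. None of the 7 held with an estimated correlation (adjusted p = 0.595 for immediate early and Nrf2 genes, 0.733 for ribosomal, 0.735 for oxidative phosphorylation, 0.785 for cholesterol and autophagy, and 0.794 for interferon genes, each the highest over all alternatives). With length and GC trends removed, the ribosomal median was 0.134 and the oxidative phosphorylation median 0.0748, and without low-dose replicate 2 the medians were 0.18 for ribosomal, 0.15 for oxidative phosphorylation and 0.12 for autophagy and lysosome genes. The macrophage list rose by 0.49, and by 0.10 without low-dose replicate 1 (adjusted p = 0.594; adjusted p = 0.785 with an estimated correlation; 4.46e-09 to 0.785 over all alternatives), and by 0.32 without control replicate 3. Adjusted over the list alone, Rps14 passed as 1 of 34, Cox6b1 and Ndufa2 as 2 of 31, and Atg5 and Ctsd as 2 of 24, against 0 over all genes. No gene passed edgeR (smallest adjusted p = 0.115), with 1773 genes at an unadjusted p under 0.05 (868 higher and 905 lower), or 1254 with only the 6 libraries compared, 900 without low-dose replicate 2, 1047 and 996 without control replicates 1 and 2, and 3525 without low-dose replicate 1, 71 called by DESeq2 and 0 by limma-voom with quality weights; without low-dose replicate 1 edgeR called 652, but 22 once length and GC trends were removed and 956 with the muscle score as a covariate. Dnase1l3 stood at -3.71 (SE 0.55) and Mgat3 at -0.55 (SE 0.11). The acute-phase inhibitor Serpina3n stood at 1.49 (SE 0.28). The groups did not overlap for 17.4% of genes, against 10% by chance.

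In high-dose tumours compared with controls, Nrf2 targets were higher by a median of 0.23 in 18 of 19 members, with Hmox1 at 1.38 (SE 0.45), or 0.79 without high-dose replicate 1. The list rose in camera (adjusted p = 1.34e-07; adjusted p = 0.3 with an estimated correlation), the 1 call of 15 that held without any 1 of the 6 libraries, with a median of 0.15 without high-dose replicate 1, and 0 of its 19 members passed adjusted over the list alone. Without high-dose replicate 1, 12 of the 15 calls ended or turned. Red blood cell genes rose by 1.86 and stood at -0.00866 without that library (adjusted p = 0.244) and at 1.8 without control replicate 1 (adjusted p = 0.164). Macrophage genes rose by 0.27, and stood at -0.02 without high-dose replicate 1 (adjusted p = 0.635) and at 0.42 without high-dose replicate 3. For red blood cells and macrophages the adjusted p = 0.726 with an estimated correlation, and over all alternatives the adjusted p of the Nrf2, red blood cell and macrophage lists ranged from 1.63e-11 to 0.97. No gene passed edgeR (smallest adjusted p = 1), with 140 genes at an unadjusted p under 0.05 (78 higher and 62 lower) and 0 called by limma-voom with quality weights; DESeq2 called 1, Tmem254c, which stood at -4.28 (SE 1.09) in edgeR. The groups did not overlap for 8.7% of genes, against 10% by chance.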

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

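The tests of a wrong label, of the immediate early response and of the muscle split were chosen only after the result was seen, as were the length and GC offsets, the muscle covariate and the use of libraries as replicates for the error of list means.

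Compared directly, the doses differed in 14 gene lists called by camera with a preset correlation, all given here. Lower at the high dose were ribosomal protein genes (median log2 fold change -0.397), immediate early genes (-0.497), oxidative phosphorylation (-0.222), glycolysis enzymes (-0.398), autophagy and lysosome genes (-0.199), and the hypoxia response (-0.42). Higher were cholesterol synthesis (0.394), endothelial genes (0.449), dendritic cells (0.723), type I interferon genes (0.516), and pericytes (0.637). Also higher were interferon-gamma and antigen presentation genes (0.287), fatty acid synthesis (0.184), and G2 and M phase genes (0.14). None of the 14 held with an estimated correlation (adjusted p = 0.396 to 0.823). With each library's length and GC trends removed, the ribosomal median was -0.185, the oxidative phosphorylation median -0.0554 and the G2 and M phase median 0.0746, the last without a call (adjusted p = 0.0551). With the muscle score as a covariate the call ended for interferon-gamma at 0.176 and G2 and M phase at 0.0906 (adjusted p = 0.151 and 0.337), and without the 3 libraries with the most muscle transcripts for hypoxia at -0.0705, type I interferon at 0.102 and interferon-gamma at 0.136 (adjusted p = 0.736, 0.748 and 0.625).

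Of these 14 lists, 8 lost the call without 1 library. Without high-dose replicate 2 the median was 0.15 for cholesterol synthesis (adjusted p = 0.14), 0.0857 for type I interferon (adjusted p = 0.866), -0.0304 for interferon-gamma (adjusted p = 0.866), 0.105 for fatty acid synthesis (adjusted p = 0.398) and 0.0316 for G2 and M phase (adjusted p = 0.821). Without low-dose replicate 3 it was -0.23 for glycolysis (adjusted p = 0.199) and -0.0719 for hypoxia (adjusted p = 0.977), where camera gave the opposite direction. Without low-dose replicate 2 it was -0.0648 for autophagy (adjusted p = 0.0714), 0.181 for interferon-gamma (adjusted p = 0.11) and 0.0628 for G2 and M phase (adjusted p = 0.118). With low-dose replicate 1 left out it was 0.136 for fatty acid synthesis (adjusted p = 0.299) and 0.0166 for G2 and M phase (adjusted p = 0.774), again with the opposite direction in camera, and without high-dose replicate 3 it was 0.132 for G2 and M phase (adjusted p = 0.0864). Sizes also moved while the call held. The median without low-dose replicate 1 was -0.659 for glycolysis, -0.675 for hypoxia and 0.45 for interferon-gamma, and without low-dose replicate 3 it was 0.44 for interferon-gamma, 0.325 for fatty acid synthesis and 0.332 for G2 and M phase. It was 0.338 for type I interferon without low-dose replicate 2, 0.231 for G2 and M phase without high-dose replicate 1 and 0.435 for interferon-gamma without high-dose replicate 3. Over all alternatives the adjusted p of the 8 lists ranged from 1.32e-10 for glycolysis to 0.977 for hypoxia.

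Without low-dose replicate 1, edgeR called 1244 genes for the low dose against stress. With all libraries edgeR called 0, DESeq2 95 and limma-voom with quality weights 0, and 1796 genes had an unadjusted p under 0.05. Skeletal muscle is argued against as the cause, since 1241 genes were called with the muscle score as a covariate. Length and GC trends may account for a large part: 175 genes were called once they were removed. Over the 1244 genes the median absolute log2 fold change went from 0.585 (median SE 0.133) to 0.38 (median SE 0.124), 1235 kept their sign, and 141 were still called, so the smaller size and not a larger error ended most calls. A wrong label on low-dose replicate 1 stays open: its mean distance to the other low-dose libraries was 2.24, against 1.73 to the stress group and 1.4 to high-dose replicate 1. With that library its dispersion index was 10, against 72.2 and 80.9 with low-dose replicates 2 and 3. But 9 of 12 libraries lay nearer to another group than to their own, and that criterion was set after the distances were seen. An effect of the low dose itself also stays open, as untested.

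Skeletal muscle transcripts were high in control replicate 1, low-dose replicate 3 and high-dose replicate 2. Muscle tissue carried along in these specimens is a candidate source, since 80% of the 25 list members had these 3 libraries highest and Acta1 reached 125 CPM there. The treatment group is argued against, since the score ranged over 5.31 within a group and over 1.61 between group means.

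Glucocorticoid-induced and cAMP targets were higher under stress, with 24 of 29 members higher and a mean log2 fold change of 0.247 (SE over libraries 0.074). The bound for arguing against a cause, 0.123 exceeded by more than the SE over libraries, was set after the means were seen. By it, muscle is argued against as the main cause. T cells with macrophages passed it only narrowly, so they stay open. The mean was 0.259 (SE 0.081) with the muscle score as a covariate, and 0.214 (SE 0.078) with the mean T cell and macrophage score. With members as replicates the SE was 0.118 for the latter, which would not pass. An immediate early response to handling stays open. The mean of 21 such genes outside the 2 lists was 0.13 (SE over libraries 0.224), too uncertain to tell. The whole list had a median of 0.0072 (adjusted p = 0.88). Other leukocytes, not tested, stay open, as does a response to the stress itself, since technical explanations were not all excluded.

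With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The number of lists called in the real split and in the highest other split was 21 and 20 for stress against control, where 1 split gave as many, the real one, 13 and 21 for the low dose against stress (9 splits, the real one included here and below), and 11 and 24 for the high dose against stress (10 splits). It was 14 and 24 for the doses against each other (7 splits), 17 and 17 for the low dose against control (2 splits), and 15 and 21 for the high dose against control (5 splits). For genes the count of splits says nothing, since with a real count of 0 by edgeR all 10 splits must give as many in each comparison, where the unadjusted p was under 0.05 for 383, 1796, 191, 860, 1773 and 140 genes and DESeq2 called 1, 95, 0, 5, 71 and 1. The highest other split gave 0 for stress against control, 49 for the low dose against stress, 0 for the high dose against stress, 1603 for the doses against each other, and 0 for each dose against control. The split with 1603 set low-dose replicate 1 and high-dose replicates 1 and 3 against the others, and the one with 49 set stress replicates 1 and 2 and low-dose replicate 1 against the others, which points to a structure of the samples across the groups.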

How the results depend on the processing

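The offsets for length and GC content, the muscle score as a covariate, the omission of the 3 libraries with the most muscle transcripts, and their combinations with the omission of low-dose replicate 1 were chosen only after the result was seen; the other alternatives were chosen before. Unless given, causes were not tested.

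By edgeR no gene passed in any of the 6 comparisons with RLE factors, without a filter, with the stricter filter, with the muscle score or with the offsets, where the counts at an unadjusted p under 0.05 in the fit of all libraries were 383, 1796, 191, 860, 1773 and 140. The replicate number as a block (replicate block) and limma-voom with quality weights also gave 0. DESeq2 called 1 gene for stress against control, 95 for the low dose against stress, 0 for the high dose against stress, 5 for the doses against each other, 71 for the low dose against control and 1 for the high dose against control. In the same order, an unadjusted p under 0.05 with an absolute log2 fold change of at least 1 gave 91, 224, 35, 111, 178 and 45 genes, a count without adjustment for the number of tests. With only the 6 libraries compared, 1 gene passed for the high dose against control and 0 in the other comparisons. Without the 3 libraries with the most muscle transcripts, 1 gene, Aspn, passed for the low dose against control and 0 elsewhere.

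Without each library in turn the counts ran from 0 to 1244 for the low dose against stress, from 0 to 99 for the doses against each other and from 0 to 652 for the low dose against control, with the highest value each time without low-dose replicate 1; without any other single library the count was 0, and for the other 3 comparisons it was 0 throughout. The count at an unadjusted p under 0.05 ran from 228 to 735 for stress against control, from 101 to 422 for the high dose against stress and from 68 to 329 for the high dose against control. Without low-dose replicate 1 and with the muscle score as a covariate the counts were 1241, 369 and 956. Without it and with the offsets they were 175, 0 and 22, of which 141, 0 and 19 were among the genes called without the offsets. DESeq2 with all libraries shared 83 of its 95 genes, 4 of its 5 and 56 of its 71 with edgeR without low-dose replicate 1. In data simulated for stress against control, edgeR called 19.4% of genes changed 1.5-fold, so most such changes would be missed there. The other comparisons were not simulated this way.

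The opposition of the stress and low-dose responses had a covariance of -0.0736, and the lowest size with different stress libraries on each side was -0.0122, with stress replicates 2 and 3 set against the controls. Without each library in turn it ran from -0.228 to -0.01005, and for the high dose from -0.2794 to -0.02606. A negative value alone shows no opposition, since the shared stress libraries give about -0.0619 and -0.0626 without any effect. Set beside simulations without the same library, the low-dose value lay below the simulated range in 4 of 9 omissions, and above it without low-dose replicate 3 or stress replicate 3. The high-dose value lay below it in 6 of 9, and above it without control replicate 1 or high-dose replicate 2. Lying outside the range thus does not show opposition. The covariance over genes that passed for stress against control could not be computed, since 0 genes passed by edgeR, with 383 at an unadjusted p under 0.05 and 1 by DESeq2.

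Each gene list was also summarised by the number of the 6 comparisons in which camera called it. With an estimated correlation, and by fry, the number was 0 for every list. Without the 3 libraries with the most muscle transcripts the number was 4 for the glucocorticoid-induced genes, 3 for stress hormone receptors and regulators, 5 for S phase, 3 for hypoxia, 0 for ferroptosis, 5 for fatty acid synthesis, 2 for fatty acid oxidation, 2 for Wnt targets, 0 for NF-kappa-B, 2 for B cells, 1 for neutrophils, 4 for fibroblasts, 3 for pericytes and 1 for colorectal epithelial genes. With the muscle score as a covariate it was 1 for stress hormone receptors and regulators, 4 for the unfolded protein response, 0 for Wnt targets, 1 for ERK output, 1 for interferon-gamma genes, 2 for T cells, 4 for fibroblasts, 0 for skeletal muscle, which the covariate itself removes, 2 for red blood cells and 1 for colorectal epithelial genes. With the length and GC offsets it was 1 for stress hormone receptors and regulators, 1 for the unfolded protein response, 0 for ferroptosis, 1 for fatty acid synthesis, 3 for epithelial-mesenchymal transition, 0 for NF-kappa-B, 2 for T cells, 1 for regulatory T cells, 4 for cytotoxic cells, 4 for fibroblasts, 4 for skeletal muscle and 2 for red blood cells. With the replicate block it was 2 for epithelial-mesenchymal transition, 2 for T cells and 2 for skin, and with RLE factors 4 for cytotoxic cells.

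Without each library in turn the number of comparisons ran from 0 to 1 for stress hormone receptors and regulators, apoptosis, adipocytes, nerve, histone and sex-linked genes. It ran from 0 to 2 for Wnt targets, the Toll-like receptor pathway, B cells and skin, and from 0 to 3 for S phase, ferroptosis, fatty acid oxidation, ERK output, epithelial-mesenchymal transition, STAT3, T cells, regulatory T cells, neutrophils, red blood cells and colorectal epithelial genes. It ran from 0 to 4 for the unfolded protein response, fatty acid synthesis and NF-kappa-B, from 1 to 3 for cAMP targets, TGF-beta targets and pericytes, and from 1 to 4 for autophagy, cytotoxic cells, mast cells and fibroblasts. It ran from 1 to 5 for interferon-gamma genes, from 2 to 4 for glucocorticoid-induced genes and skeletal muscle, from 2 to 5 for G2 and M phase, type I interferon and macrophages, from 3 to 5 for immediate early genes and from 3 to 6 for hypoxia.

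Of 1183 values of called lists under the alternatives, 827 kept their direction and call, 344 lost the call and 12 reversed. Of these, estimated correlation and fry keep the fit and ended every call. Of the 546 values without 1 library, 134 ended or turned the call, and in 100 more the median moved by over 1.5 times with the call kept. Of 2962 values of named genes, 2819 kept their direction and their side of the threshold, 138 passed where they had not, and 5 reversed. Of 1056 values of named genes without 1 library, 89 moved by over 1.5 times. Without the 3 libraries with the most muscle transcripts, heat shock proteins stood at -0.0759 and NF-kappa-B genes at 0.0285 in the high dose against control, the latter with camera's direction reversed. With the offsets and without low-dose replicate 1, Cenpf stood at -0.009349 between the doses.

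For stress against control, the medians without each library in turn ran from -0.232 to 0.0503 for G2 and M phase and from -0.402 to 0.0956 for cholesterol synthesis, both positive without stress replicate 2, and from -0.554 to 0.215 for interferon-gamma genes, positive without stress replicate 3. Type I interferon genes ran from -0.895 to -0.121 in the low dose against stress, where camera's direction reversed without stress replicate 2. In the high dose against stress, T cells ran from -0.723 to 0.185, positive without stress replicate 1, and skeletal muscle from -0.416 to 5.31, negative without high-dose replicate 2. Between the doses, G2 and M phase ran from 0.0166 to 0.332 and hypoxia from -0.675 to -0.0719, with camera's direction reversed without low-dose replicate 1 and low-dose replicate 3. In the high dose against control, heat shock proteins ran from -0.0786 to 0.257 and red blood cells from -0.00866 to 2.39, negative without high-dose replicate 2 and high-dose replicate 1. Among genes, Myh7 ran from -8.681 to 1.145 in stress against control, positive without control replicate 1. In the high dose against stress, Pvalb ran from -3.171 to 9.657, negative without high-dose replicate 2, Cxcl1 from -1.685 to 0.189, positive without stress replicate 3, and Fasl from -1.158 to 0.2758, positive without stress replicate 1.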

Other observations

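The muscle, length and GC alternatives, and genes singled out by single libraries, were chosen after the result was seen.

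Chil3, a chitinase-like protein of alternatively activated macrophages, stood at 31.8 ± 45.4 CPM in the low-dose group and 1.16 ± 0.614 CPM under stress, a log2 fold change of 4.76 (SE 1.25). In low-dose replicate 3 Chil3 was at 84.17 CPM, against 7.866 and 3.277 in the other low-dose libraries. Adra2a, an alpha-adrenergic receptor that responds to noradrenaline, stood at 2.4 ± 0.441 CPM in the low-dose group and 0.848 ± 0.434 CPM under stress, a log2 fold change of 1.49 (SE 0.48), and at 0.99 (SE 0.48) for the high dose. Cxcl1, a neutrophil chemokine, stood at 1.53 (SE 0.66) for stress against control, with stress replicate 3 at 13.29 CPM and the other stress libraries at 2.041 and 2.215 CPM. None of these genes passed by edgeR.

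For stress against control, 8 lists were called that lost the call without at least 1 library. The unfolded protein response rose by 0.104, and stood at 0.0362 without stress replicate 3, 0.0566 without control replicate 2, 0.097 without control replicate 1 and 0.104 without stress replicate 2 (adjusted p = 0.434, 0.412, 0.139 and 0.149). Cholesterol synthesis fell by 0.116, and stood at 0.0158 without control replicate 2, -0.0493 without stress replicate 1 and 0.0956 without stress replicate 2 (adjusted p = 0.786, 0.154 and 0.624). G2 and M phase genes fell by 0.0896, and stood at -0.0655 without control replicate 2, -0.0903 without stress replicate 1 and 0.0503 without stress replicate 2 (adjusted p = 0.211, 0.0591 and 0.616). Interferon-gamma genes fell by 0.103 and stood at -0.00368 without control replicate 3, -0.0469 without stress replicate 2 and 0.215 without stress replicate 3 (adjusted p = 0.596, 0.107 and 0.00112). Skin genes fell by 0.324, and stood at -0.184 without control replicate 1, -0.141 without control replicate 3 and -0.0154 without stress replicate 1 (adjusted p = 0.176, 0.24 and 0.818). Nerve genes fell by 0.0459, with Ncam1 at -1.34 (SE 0.35), which passed when adjusted over the list alone as 1 of 12, and stood at -0.0256 without control replicate 2, -0.214 without stress replicate 1 and 0.03 without stress replicate 3 (adjusted p = 0.211, 0.0636 and 0.201). Histone genes fell by 0.218 and lost the call without control replicate 2, stress replicate 1 or stress replicate 2 (adjusted p = 0.214, 0.247 and 0.135). Wnt targets fell by 0.227 and lost the call without control replicates 2 or 3 or any stress replicate (adjusted p = 0.0785, 0.128, 0.111, 0.135 and 0.0612). With the call kept, the median was -0.255 for cholesterol and -0.0985 for nerve genes without control replicate 1, -0.195 for interferon-gamma without control replicate 2, 0.182 for the unfolded protein response without control replicate 3, and 0.246 for the latter and -0.554 for interferon-gamma without stress replicate 1. It was -0.128 for nerve genes without stress replicate 2, and without stress replicate 3 -0.402 for cholesterol, -0.232 for G2 and M phase and -0.127 for histones. The muscle score as a covariate ended the call for cholesterol at -0.0726, G2 and M phase at -0.013, interferon-gamma at 0.00364 and Wnt targets at -0.151 (adjusted p = 0.107, 0.58, 0.639 and 0.102), and omitting the 3 libraries with the most muscle transcripts ended it for the unfolded protein response at 0.0968 (adjusted p = 0.19). With an estimated correlation the lowest adjusted p of the 8 lists was 0.326, and the range over all their alternatives was 1.8e-16 to 0.988.

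For the low dose against control, 9 more lists were called. Fibroblast and matrix genes rose by 0.336, epithelial-mesenchymal transition genes by 0.269, heat shock proteins by 0.294, the unfolded protein response by 0.192 and ferroptosis regulators by 0.245. G2 and M phase genes fell, at -0.271, as did interferon-gamma genes at -0.393, fatty acid synthesis at -0.224 and dendritic cells at -0.493. Without low-dose replicate 1 the call ended for G2 and M phase at -0.117, epithelial-mesenchymal transition at 0.169, fatty acid synthesis at -0.202 and fibroblasts at 0.314 (adjusted p = 0.217, 0.217, 0.245 and 0.314). Without low-dose replicate 2 it ended for dendritic cells at -0.338, ferroptosis at 0.152, heat shock proteins at 0.169 and the unfolded protein response at 0.0995 (adjusted p = 0.108, 0.076, 0.116 and 0.26). Without low-dose replicate 3 it ended for ferroptosis at 0.181 and the unfolded protein response at 0.139 (adjusted p = 0.0586 and 0.31). Without control replicate 1 it ended for ferroptosis at 0.284 and the unfolded protein response at 0.168, without control replicate 2 for dendritic cells at -0.468, fatty acid synthesis at -0.148 and the unfolded protein response at 0.143, and without control replicate 3 for interferon-gamma genes at -0.29 (highest adjusted p = 0.139). With the call kept, the median without low-dose replicate 1 was 0.473 for heat shock proteins, -0.75 for dendritic cells, 0.343 for the unfolded protein response and 0.387 for ferroptosis, for dendritic cells -0.257 without control replicate 1, and for G2 and M phase -0.47 without low-dose replicate 3. With length and GC trends removed the call ended for the unfolded protein response, ferroptosis and fatty acid synthesis (highest adjusted p = 0.103). Pdpn passed when adjusted over the fibroblast list alone, as 1 of 25. The estimated correlation gave adjusted p-values from 0.595 to 0.794, and all their alternatives together from 3.8e-14 to 0.794.

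For the high dose against control, 12 more lists were called. Endothelial genes rose by 0.338, fibroblasts by 0.212, mast cells by 0.731, heat shock proteins by 0.147, B cells by 0.376, cytotoxic cells by 0.306, oxidative phosphorylation by 0.046, NF-kappa-B genes by 0.0907 and ferroptosis regulators by 0.113. G2 and M phase genes fell, at -0.163, as did hypoxia at -0.173 and glycolysis at -0.168. Oxidative phosphorylation stood at 0.0161 to 0.0814 without 1 library, NF-kappa-B at 0.0338 to 0.224 and ferroptosis at -0.016 to 0.252. Each of these 3 was highest without high-dose replicate 3 and lost the call without control replicates 1 or 2 or high-dose replicates 1 or 2 (highest adjusted p = 0.91). Mast cell genes stood at 1.17 to 1.59, where members may differ, without any 1 library but high-dose replicate 1. Without it they stood at 0.205, which ended the call (adjusted p = 0.361). The call also ended without that library for G2 and M phase at -0.0597, fibroblasts at 0.0684, B cells at 0.101, hypoxia at -0.127, glycolysis at -0.0902 and cytotoxic cells at 0.209 (highest adjusted p = 0.231). Endothelial genes stood at 0.15 without control replicate 3, which ended the call (adjusted p = 0.112), at 0.527 without control replicate 1 and at 0.508 without high-dose replicate 3. Heat shock proteins stood at -0.0786 without high-dose replicate 2 and 0.0791 without control replicate 2, without a call (adjusted p = 0.325 and 0.14), and at 0.253 and 0.257 without high-dose replicates 1 and 3. Hypoxia at -0.0385 and glycolysis at -0.0988 lost the call without control replicate 2, as did glycolysis at -0.0989 without high-dose replicate 3 (highest adjusted p = 0.268), while hypoxia stood at -0.26 without control replicate 1, and glycolysis at -0.311 and G2 and M phase at -0.265 without high-dose replicate 2. Cytotoxic cells lost it at 0.268, 0.254 and 0.274 without control replicates 1 or 3 or high-dose replicate 3 (highest adjusted p = 0.156). With length and GC trends removed the calls of oxidative phosphorylation, ferroptosis and NF-kappa-B ended (highest adjusted p = 0.575), as did the first and last with the muscle score (adjusted p = 0.051 and 0.0725). The estimated correlation gave adjusted p-values from 0.3 to 0.854, and all their alternatives together from 5.49e-13 to 0.97.

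Camera called 14 lists in no comparison, and their lowest adjusted p over the 6 comparisons is given here with its median. It was 0.0817 for stress hormone receptors and regulators (0.0681, high dose against stress), 0.0851 for S phase (0.0773, high dose against stress), 0.0946 for neutrophils (0.823, low dose against control) and 0.138 for regulatory T cells (-0.304, low dose against stress). It was 0.211 for adipocytes (0.126, high dose against control), 0.218 for the Toll-like receptor pathway (0.0827, high dose against control), 0.247 for STAT3 (0.189, low dose against stress) and 0.252 for fatty acid oxidation (0.0799, low dose against control). It was 0.341 for aryl hydrocarbon receptor targets (0.151, high dose against control), 0.409 for apoptosis (0.0594, high dose against control), 0.424 for drug-target hubs (-0.0563, between the doses), 0.503 for p53 targets (0.0272, low dose against stress), 0.524 for sex-linked genes (-0.152, low dose against stress) and 0.661 for circadian clock genes (-0.0379, high dose against stress).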
